A study of Arabidopsis thaliana with 8 samples.

How the data were processed

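Total RNA from whole 7-day-old Arabidopsis seedlings was measured on Affymetrix arrays, 2 arrays in each of 4 groups, and labelling, hybridization and scanning were done by the NASC service, per the labels' protocols. The deposited values are log2 expression values from RMA (robust multi-array averaging), which corrects background, normalizes the arrays together and summarises the probes of a probe set. Per the submitters' processing notes, the authors made them in Affymetrix Expression Console 1.4 and compared groups in Transcriptome Analysis Console 3.1. The raw array files were not analysed here, and all results start from the deposited log2 table, which held 38408 probe sets on 8 arrays. Groups were taken from the sample labels.

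Probe sets were named with the annotation given, whose array build was not stated; names were matched by Entrez ID to the RefSeq annotation of assembly GCF_000001735.4 (TAIR10.1), used for names only. The annotation listed 17504 probe sets, of which 758 were paired with several genes and left out of the gene tests, and 20904 were not listed. The 16746 probe sets paired with exactly 1 gene gave 16554 genes, with the brightest probe set taken for the 163 genes that had more than 1. Of these genes 1803 had a symbol other than the locus code. The 21662 probe sets outside the gene tests were tested apart. FH1 had 0 listed probe sets.

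Group means were compared with limma 3.58.1 in R 4.3.3, in a linear model of all 8 arrays with empirical Bayes moderation (4 residual and 5.81 prior degrees of freedom). The Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. The contrasts were fh1-1 against wild type on solid medium, SMIFH2 against control in liquid medium, liquid against solid medium in wild type, and the difference between the SMIFH2 and fh1-1 effects. The number of arrays limits the precision. Effects were compared across genes by Pearson and Spearman correlation, covariance and Fisher's exact test on the calls; values for unchanged groups that share control arrays came from 20 simulations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

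Before the data were examined, 35 gene lists with 1258 members were fixed, of which 201 were measured. The 18 lists with at least 5 measured members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast; the other 17 had too few members and got no test. Member counts are given over all genes and adjusted over the list alone. The root markers that were measured are 6 beta-glucosidase and lectin genes, and 3 of the 9 shoot markers are also photosynthesis genes.

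The genes named in the text follow a rule that was also fixed before the data were examined. Named in each contrast were the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, arrays of the 2 groups that did not overlap, and a symbol other than the locus code. The condition on overlap cannot be applied to the difference of effects. Added to these were up to 2 genes from each list that passed or had at least 5 members past the threshold, and, for the correlation, the 8 genes past the threshold in both effects with the largest summed change. Other list members are given as examples and were chosen after their values were seen, and so was the run of the alternatives on them. FLP1 and RTFL7 had no RefSeq match and are given without a locus.

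The steps were tested on simulated data with 16554 genes, of which 200 were changed, 50 at each of 4 fold changes. For fh1-1, limma recovered 8 of 50 genes changed 1.5-fold, 40 changed 2-fold and 50 changed 4-fold, with 10 false calls among 158. For SMIFH2 these numbers were 9, 44 and 50, with 12 false calls among 165, and for the medium 8, 41 and 50, with 12 among 161. For the difference of effects they were 1, 18 and 50, with 9 among 128. With no changed genes there were 0 calls in each. A list of 11 members shifted by 1 was found, and 0 other lists were called. The simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes.

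Alternatives fixed before the data were examined were a fit of only the 4 arrays compared, the repeat number as a block, every probe set, omission of the third of probe sets with the lowest mean level, cyclic loess, quantile normalization, and an intensity-trended robust prior. The mean of a gene's probe sets, 2 thresholds with a 2-fold change, omission of each array in turn, camera with an estimated correlation, and fry in limma were tried as well. The third with the lowest mean level was taken from the probe sets of the 16554 genes tested. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the other groups.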

Results

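Gene expression was measured on Affymetrix arrays in pools of whole Arabidopsis thaliana seedlings of the Columbia background, with about 120 seedlings per pool. There were 4 groups of 2 arrays, and the arrays of a group held separate pools described as biological replicates. The study asked how impaired formins alter transcript levels; formins are proteins that start and lengthen actin filaments. Impairment came either from the fh1-1 mutation in FH1, the gene of a membrane-anchored formin, or from 20 uM SMIFH2, a small-molecule inhibitor of the formin FH2 domain. The mutant and its wild-type sister line stayed on solid medium for 7 days in cycles of 16 h light and 8 h dark. The other 2 groups were wild-type seedlings moved after 6 days on solid medium to liquid medium for 1 day in continuous light, with or without SMIFH2. Whether this liquid control received the solvent of SMIFH2 was not given in the sources used here. Values are log2 expression, and a change of 1 is a doubling.

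The arrays had median log2 values from 3.89 to 3.96, and 16554 named genes were tested. With 2 arrays per group, the median standard error of a log2 fold change was 0.18, which gives a 95% interval of about 0.40 on either side. Across genes, arrays of one group correlated at r = 0.977 to 0.986. Arrays of fh1-1 on solid medium and of SMIFH2 in liquid medium correlated at r = 0.981 to 0.983, within that range, although they differed in genotype, medium and light. Wild-type arrays on solid medium correlated with fh1-1 arrays at r = 0.945 to 0.954, and liquid control arrays with SMIFH2 arrays at r = 0.955 to 0.965. The first principal component held 47.7% of the variance and separated the 4 arrays of fh1-1 and SMIFH2 (scores of -0.37 to -0.33) from the 4 untreated wild-type arrays (0.22 to 0.47).

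The first comparison asked what the fh1-1 mutation changed on solid medium. No probe set was listed for FH1 itself, so the mutant label could not be checked against its transcript. Of 11 photosynthesis genes 10 rose in the mutant (list adjusted p = 1.2e-11, and adjusted p = 0.039 with an estimated correlation). LHB1B2 (AT2G34420), a light-harvesting chlorophyll-binding protein of photosystem II, rose by 4.83 ± 0.18 on the log2 scale (SE, n = 2 arrays per group), from a mean of 6.01 to 10.84. PSAN (AT5G64040), a subunit of photosystem I, rose by 3.16 ± 0.16. The largest rise among genes with a symbol was that of THI2.2 (AT5G36910), an antimicrobial thionin, at 5.77 ± 0.20, over a wild-type mean of 2.13, with the 25th percentile of the arrays at 2.13 to 2.24. GSTU20 (AT1G78370), a glutathione S-transferase, rose by 4.92 ± 0.26. PIF7 (AT5G61270), a transcription factor that binds phytochrome, rose from a mean of 2.59 to 6.79 (SE of the change 0.16). MGL (AT1G64660), the methionine gamma-lyase that breaks down methionine, fell by 3.90 ± 0.19 from a mean of 8.13 to 4.22, and FLP1 fell by 4.07 ± 0.28 to a mean of 2.36, just above that percentile.

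Other genes among the 8 largest rises were AOP3 (AT4G03050), a dioxygenase of glucosinolate side-chain synthesis, at 4.48 ± 0.50, ECS1 (AT1G31580), a cell wall protein, at 4.36 ± 0.47, and MSRB6 (AT4G04840), a methionine sulfoxide reductase, at 3.27 ± 0.22. The other large falls included the subtilisin-like proteases SBT4.12 (AT5G59090) at -2.80 ± 0.24 and ATSBT5.2 (AT1G20160) at -2.61 ± 0.17. The kinase gene WNK9 (AT5G28080) changed by -2.60 ± 0.19, IAA20 (AT2G46990), an auxin-response repressor, by -2.40 ± 0.23, to a mean of 1.71 that was not shown to be above background, and ALDH7B4 (AT1G54100), an aldehyde dehydrogenase, by -2.23 ± 0.15. All of these passed limma's test at adjusted p values from 6.7e-07 to 0.00018. M17 (AT2G41260), a late embryogenesis abundant protein gene, changed by -2.53 ± 0.63 at adjusted p = 0.017. Its change was -3.22 without array 1 of wild type on solid medium and -1.85 without array 2. Without array 2 of wild type on solid medium its adjusted p was 0.14, without array 2 of fh1-1 it was 0.11, over every probe set it was 0.069, and over 16 alternative settings it ranged from 0.0022 to 0.14.

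In all, 3734 of the 16554 genes passed at an adjusted p under 0.05 in limma, 1800 higher and 1934 lower in fh1-1. Of these, 842 were at least 2-fold higher and 575 at least 2-fold lower. The number that passed was lower without any single array of these 2 groups, a fit that leaves 1 array in that group. It was also lower without either SMIFH2 array, and higher without either liquid control array. Tested over every probe set on the array, named or not, 6205 probe sets passed. The share of higher genes among the 3734, 48.2%, was 51.9% with cyclic loess, 51.2% over every probe set and 55.4% without array 1 of fh1-1, and neither direction prevailed throughout.

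Among the gene lists fixed before the data were examined, the photosynthesis list had 10 of its 11 measured members higher in fh1-1 and 0 lower, also 10 when adjusted over the list alone. Its median change was 1.75 (SD 1.32), and the list test gave an adjusted p of 1.2e-11. Of the lists fixed beforehand, this was the only call in any comparison that held with an estimated correlation between genes (adjusted p = 0.039 with an estimated correlation). The photosystem subunits PSBW (2.66 ± 0.15) and PSAE-1 (2.09 ± 0.15) rose with LHB1B2 and PSAN, while LHCB4.3, at a low mean level of 2.72, changed by 0.08 ± 0.21 and did not pass. The shoot markers had 7 of 9 members higher, also 7 over the list alone, with a median of 1.13 and an adjusted p of 1.8e-06 (adjusted p = 0.18 with an estimated correlation). Of these 9, the Calvin cycle enzyme SBPASE (2.56 ± 0.15), Rubisco activase RCA (1.75 ± 0.14) and PRK (1.18 ± 0.14) belong to the photosynthesis list too. The stomatal lineage regulators SPCH (1.13 ± 0.19) and FMA (1.11 ± 0.18) also rose, whereas the leaf polarity genes YAB2 (0.36 ± 0.20) and YAB3 (0.03 ± 0.18) did not pass.

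The root markers moved the other way, with 3 of 6 members lower, also 3 over the list alone, a median of -0.48 and an adjusted p of 0.039 (adjusted p = 0.46 with an estimated correlation). BGLU22 (AT1G66280), a beta-glucosidase, changed by -0.85 ± 0.17, JAL33 (AT3G16450), a jacalin-related lectin, by -0.71 ± 0.16, and JAL34 by -0.53 ± 0.14, which missed the threshold without any single array of these 2 groups (0.058 to 0.14, in a range from 0.0014 to 0.14). The very abundant PYK10, at a mean level of 12.25, changed by -0.09 ± 0.14 and did not pass. The root marker call ended without array 2 of wild type on solid medium (adjusted p = 0.15), array 1 of fh1-1 (0.066) or array 2 of fh1-1 (0.053), and also when the third of probe sets with the lowest mean level was left out (0.086). Over 18 alternatives its adjusted p ranged from 0.0064 to 0.46. JAL33 missed the threshold without array 2 of wild type on solid medium (0.051), and both JAL33 and BGLU22 missed it without array 1 of fh1-1 (0.067 each). Without array 2 of wild type on solid medium BGLU22 reached 0.05, and the adjusted p ranged from 0.0059 to 0.067 for JAL33 and from 7e-04 to 0.067 for BGLU22.

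The auxin list had 6 of 12 members lower in fh1-1, also 6 over the list alone, and 0 higher, with a median of -0.54 and an adjusted p of 0.016 (adjusted p = 0.25 with an estimated correlation). Beside IAA20, the lateral root regulators LBD16 (-1.09 ± 0.15) and LBD29 (from a mean of 5.59 to 4.60, SE of the change 0.15) fell, as did WES1 (-0.85 ± 0.17), which encodes an enzyme that conjugates auxin to amino acids. WES1 reached an adjusted p of 0.05 without array 2 of fh1-1, in a range from 0.00041 to 0.05. The list call ended without array 1 of wild type on solid medium (adjusted p = 0.1) or array 2 of fh1-1 (0.053), in a range from 0.0013 to 0.25 over 18 alternatives. In the list of abscisic acid, cold and drought genes, 3 of 6 rose, or 4 over the list alone, with a median of 0.56 and an adjusted p of 0.022 (adjusted p = 0.25 with an estimated correlation). These were the cold-regulated COR15A (2.66 ± 0.20), KIN2 (1.92 ± 0.20) and, narrowly, COR47 (0.66 ± 0.21, adjusted p = 0.049), whose wild-type arrays stood at 7.61 and 6.92. Without array 2 of wild type on solid medium COR47 gave 0.32 at an adjusted p of 0.32, and without array 1 it gave 1.01 at 0.0066. It missed the threshold without any other single array (0.056 to 0.18) and in 11 of 16 alternatives in all, in a range from 0.0066 to 0.32.

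Of the measured formins, 2 of 9 rose and 1 fell in fh1-1, with the same counts over the list alone: AT2G43800 rose by 1.19 ± 0.23, AT5G48360 by 1.00 ± 0.26, and AT2G25050 fell by 0.65 ± 0.17. AT5G48360 missed the threshold without array 2 of wild type on solid medium (0.14), without array 1 or 2 of fh1-1 (0.056 and 0.12) or over every probe set (0.063), in a range from 0.0068 to 0.14. AT2G25050 missed it without the same arrays (0.15, 0.082 and 0.12) or with the mean of its probe sets (0.14), in a range from 0.014 to 0.15. The list as a whole did not pass (median 0.16, adjusted p = 0.6). Of 9 actin cytoskeleton genes, the LIM-domain gene WLIM2a (1.02 ± 0.15) and NET1A (0.74 ± 0.16), which encodes an actin-binding membrane protein, rose, and WLIM2b (-0.87 ± 0.14) fell (list adjusted p = 0.6). NET1A missed the threshold without array 2 of fh1-1 (0.071), in a range from 0.0066 to 0.071. Of 6 microtubule genes, the tubulins TUB1 (-0.98 ± 0.21), TUB9 (-0.79 ± 0.16) and TUB6 (-0.55 ± 0.15) fell, and TUB5 (0.73 ± 0.18) rose (list adjusted p = 0.33). TUB1 missed the threshold without array 1 of wild type on solid medium (0.06) or of fh1-1 (0.083), in a range from 0.0062 to 0.083, and TUB9 without array 2 of fh1-1 (0.055), in a range from 0.00038 to 0.055. TUB6 missed it without any single array of the 2 groups (0.071 to 0.16) and TUB5 without any but array 1 of wild type (0.059 to 0.12), with lowest values of 0.0031 and 0.0068 over the alternatives. Expansins, proteins that loosen cell walls, changed in both directions, with 5 of 22 higher, among them EXPB3 (1.62 ± 0.17), and 4 lower, among them EXPA9 (-2.05 ± 0.18), or 5 and 5 over the list alone (list adjusted p = 0.94). In the xenobiotic response list 2 of 9 rose, with UGT73C6 (1.85 ± 0.21), a UDP-glycosyltransferase, the higher, and 3 fell, ALDH7B4 the furthest (list adjusted p = 0.92).

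The remaining 8 tested lists also missed the threshold in fh1-1, with list adjusted p values of 0.12 for sugar starvation genes, 0.56 for glutathione S-transferases, 0.61 for cell cycle and histone genes, 0.82 for the unfolded protein response and for touch, wound and elicitor genes, 0.84 for xyloglucan endotransglucosylases and for senescence and autophagy, and 0.85 for pollen and flower markers. Their members that passed were 1 up and 3 down of 6 (4 down over the list alone), 2 and 2 of 13, 2 and 1 of 7, 1 and 2 of 5, 3 and 1 of 8, 3 and 1 of 10, 1 and 1 of 13, and 1 and 1 of 8, in the order of the lists, with no other difference over the list alone. The xyloglucan and the touch lists had medians of -0.10 and -0.17 but means of 0.12 and 0.21, and their tests pointed up.

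**Figure D1:**
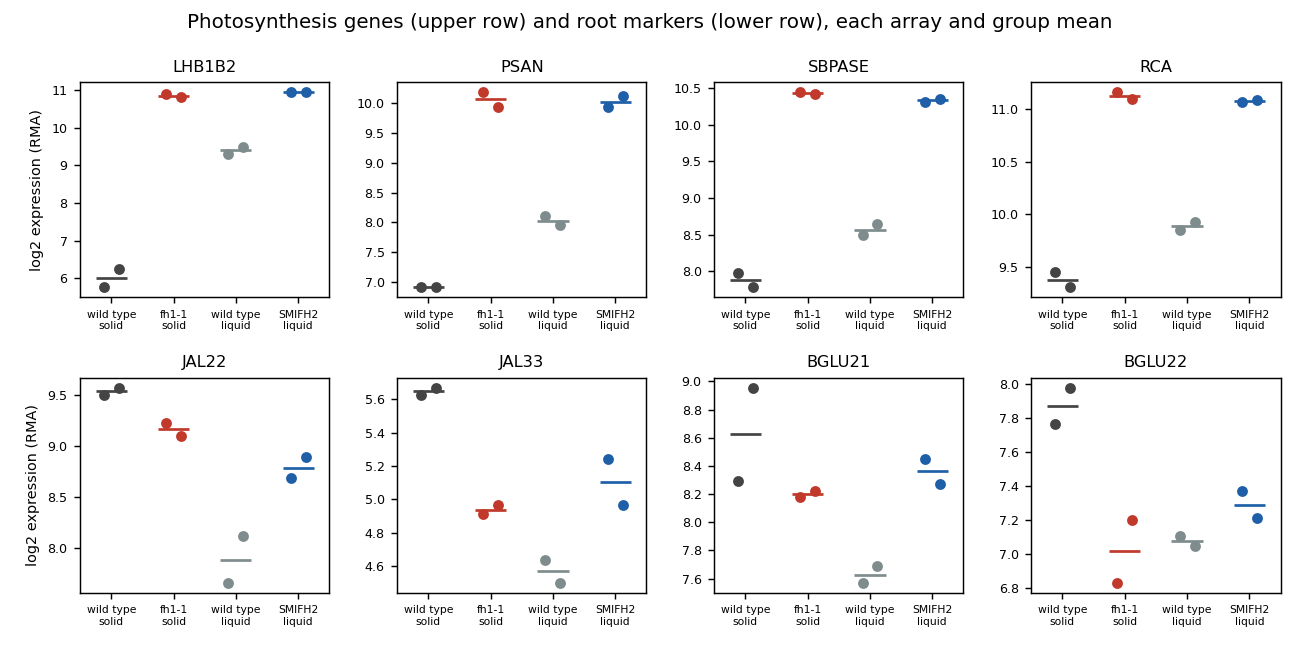
Log2 expression (vertical axis, RMA) of 4 photosynthesis genes in the upper panels and 4 root markers in the lower panels, with a point per array and a line at the mean of the 2 arrays of each group. LHB1B2 rose from a mean of 6.01 in wild type to 10.84 in fh1-1 on solid medium and from 9.40 to 10.94 with SMIFH2 in liquid medium, whereas JAL22 had its lowest mean, 7.88, in the liquid control; each panel has its own vertical range, which does not start at 0.

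The second comparison asked what 20 uM SMIFH2 changed in wild-type seedlings in liquid medium. THI2.2 again had the largest rise among genes with a symbol, 4.79 ± 0.20 (log2, SE, n = 2 arrays per group). Other large rises were those of AOP3 (4.11 ± 0.50), DFR (AT5G42800), an enzyme of anthocyanin synthesis, at 3.63 ± 0.22, PIF7 (3.58 ± 0.16) and MSRB6 (3.38 ± 0.22). The AOP3 value rested on single arrays, at 3.06 without array 1 of the liquid control, under DFR, PIF7 and MSRB6, and at 5.16 without array 2, above THI2.2. MGL fell by 3.87 ± 0.19, from a mean of 8.24 to 4.37, and FLP1 fell by 4.03 ± 0.28, to a mean of 1.80, under the 25th percentile of every array. Of 11 photosynthesis genes 8 rose, with PSAN at 2.00 ± 0.16 and SBPASE at 1.77 ± 0.15 (list adjusted p = 1.3e-09, and adjusted p = 0.056 with an estimated correlation). Of 6 sugar starvation genes 4 fell, among them MCCB (AT4G34030), a subunit of an enzyme of leucine breakdown, by 1.19 ± 0.15 (list adjusted p = 0.0066, and adjusted p = 0.26 with an estimated correlation).

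Further rises were those of GSTU20 (3.08 ± 0.26), TRXF2 (AT5G16400), a chloroplast thioredoxin, at 2.81 ± 0.25, and NdhU (AT5G21430), a subunit of the chloroplast NDH complex, at 2.61 ± 0.19. Further falls were those of COR27 (AT5G42900), a cold-regulated gene tied to the circadian clock, at -2.72 ± 0.17, EXPA16 (AT3G55500) at -2.40 ± 0.16, and ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, at -2.24 ± 0.31. ALDH7B4 changed by -2.12 ± 0.15, IAA20 by -1.83 ± 0.23 to a mean of 2.06, also under that percentile, and ATL8 (AT1G76410), a RING-type ubiquitin ligase, by -1.81 ± 0.29. The change of ICL was -1.65 without array 1 of the liquid control and -2.83 without array 2. These genes passed in limma at adjusted p values from 1.7e-06 to 0.0027. In total 2459 genes passed, 1288 higher and 1171 lower with SMIFH2, of which 565 and 351 were at least 2-fold changed. Fewer genes passed without any single one of the 8 arrays, also of the groups not compared, a fit that leaves 1 array in that group. The share of calls that were higher, 52.4%, was 49.8% with the trended robust prior and 58.6% without array 1 of SMIFH2.

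The photosynthesis list had 8 of 11 members higher with SMIFH2, or 9 over the list alone, and 0 lower, with a median of 1.16 (SD 0.56) and an adjusted p of 1.3e-09 (adjusted p = 0.056 with an estimated correlation). The shoot markers had 4 of 9 higher, or 5 over the list alone, with a median of 0.51 and an adjusted p of 0.0066 (adjusted p = 0.28 with an estimated correlation). The members that rose were SBPASE, RCA (from a mean of 9.88 to 11.08, SE of the change 0.14), PRK (0.78 ± 0.14) and HPR (1.15 ± 0.18), the photorespiratory hydroxypyruvate reductase. The stomatal and leaf polarity genes gave 0.06 ± 0.18 for FMA, 0.51 ± 0.19 for SPCH and -0.34 ± 0.20 for YAB2, none of them past the threshold. The root markers were higher too, in 3 of 6 genes or 4 over the list alone, with a median of 0.45 and an adjusted p of 0.0094 (adjusted p = 0.3 with an estimated correlation). They were JAL22 (AT2G39310) at 0.90 ± 0.18, BGLU21 (AT1G66270) at 0.73 ± 0.21 and, narrowly, JAL33 at 0.53 ± 0.16 (adjusted p = 0.046). JAL33 missed the threshold without any single one of the 8 arrays (0.059 to 0.26) and in 13 of 16 alternatives, in a range from 0.03 to 0.26. JAL22 missed the threshold without array 1 of the liquid control (0.054) or array 2 of SMIFH2 (0.068), in a range from 0.00055 to 0.068. BGLU21, at 0.042, missed it without any single array of the fh1-1 (0.068 for either), liquid control (0.16 and 0.084) or SMIFH2 group (0.2 and 0.1), over every probe set (0.1) or with quantile normalization (0.06), in a range from 0.009 to 0.2.

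The sugar starvation list had 4 of 6 members lower with SMIFH2, also 4 over the list alone, with a median of -0.65 and an adjusted p of 0.0066 (adjusted p = 0.26 with an estimated correlation). Beside MCCB these were ETFQO (-1.06 ± 0.16), which passes electrons from amino acid breakdown to ubiquinone, AKINBETA1 (-0.66 ± 0.18) and D2HGDH (-0.64 ± 0.15). AKINBETA1 missed the threshold without either fh1-1 array (0.058), array 1 of the liquid control (0.18) or array 1 or 2 of SMIFH2 (0.21 and 0.055), over every probe set (0.079) or in the fit of the 4 liquid arrays (0.078), in a range from 0.0041 to 0.21. D2HGDH missed it without any single array of these 2 liquid groups (0.052 to 0.13) or in the fit of their 4 arrays (0.052), in a range from 0.0065 to 0.13. The auxin list had 5 of 12 members lower, also 5 over the list alone, with a median of -0.31 and an adjusted p of 0.015 (adjusted p = 0.28 with an estimated correlation). These were IAA20, IAA29 (-1.17 ± 0.34), GH3.3 (-1.14 ± 0.18), WES1 (-0.92 ± 0.17) and LBD16 (-0.78 ± 0.15). IAA29 passed narrowly, at 0.045, and missed the threshold without any single array of the fh1-1 (0.066 for either), liquid control (0.2 and 0.079) or SMIFH2 group (0.16 for either) or over every probe set (0.12), in a range from 0.003 to 0.2. WES1 missed it without array 1 of SMIFH2 (0.051, in a range from 0.00033 to 0.051), and LBD16 without array 1 of the liquid control (0.052) or array 2 of SMIFH2 (0.051), in a range from 0.0054 to 0.052.

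Of the 9 formins only AT2G25050 passed with SMIFH2, at -0.79 ± 0.17, and 1 also passed over the list alone (list adjusted p = 0.93). AT2G25050 missed the threshold without array 1 of the liquid control (0.057) or of SMIFH2 (0.084), in a range from 0.0056 to 0.084. Of 22 expansins 5 rose, with EXPB3 (AT4G28250) at 2.46 ± 0.17, and 2 fell, EXPA16 and EXPA9 (-1.34 ± 0.18), with the same counts over the list alone (list adjusted p = 0.34). In the xenobiotic response list 3 of 9 rose, or 4 over the list alone, with UGT73C6 at 1.71 ± 0.21, and 2 fell (list adjusted p = 0.36). The list adjusted p was 0.063 for senescence and autophagy, 0.13 for abscisic acid, cold and drought, 0.14 for microtubule genes, 0.16 for cell cycle and histone genes, 0.27 for glutathione S-transferases and 0.31 for xyloglucan endotransglucosylases. It was 0.41 for touch, wound and elicitor genes, 0.44 for the unfolded protein response, and 0.93 for actin genes and for pollen and flower markers. Among the passing members of these lists were the tubulin TUB9 (-0.93 ± 0.16), WLIM2b (-0.77 ± 0.14) and COR15A (2.09 ± 0.20). Members past the threshold, up and down, were 1 and 2 of 13 senescence genes (1 and 4 over the list alone), 2 and 0 of 6 abscisic acid genes, 0 and 2 of 6 microtubule genes (1 and 4), 1 and 1 of 7 cell cycle genes (4 and 1), 2 and 1 of 13 glutathione S-transferases (3 and 1) and 1 and 3 of 10 xyloglucan endotransglucosylases (2 and 4). They were 2 and 0 of 8 touch genes, 1 and 1 of 5 unfolded protein response genes (1 and 2), 1 and 1 of 9 actin genes (2 and 1) and 1 and 0 of 8 pollen and flower markers. The actin list had a median of -0.09, a mean of 0.00 and a test that pointed up.

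**Figure D2:**
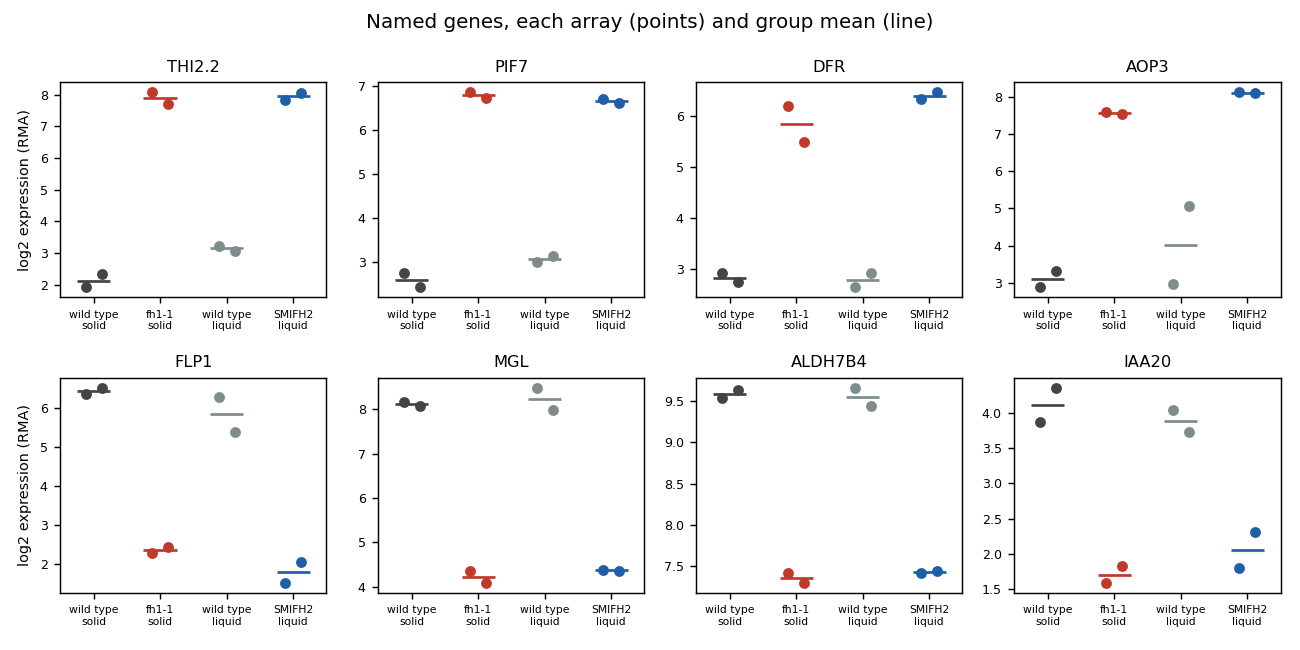
Log2 expression (vertical axis, RMA) of 8 named genes, with a point per array and a line at the mean of the 2 arrays of each group. The fh1-1 and SMIFH2 means lay near each other, at 7.90 and 7.94 for THI2.2 and at 4.22 and 4.37 for MGL, while the wild-type means were 2.13 and 3.15 for THI2.2 and 8.13 and 8.24 for MGL; each panel has its own vertical range.

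The effects of fh1-1 and of SMIFH2 were then set against each other; they have separate control arrays. The genes with the largest summed change among those past the threshold in both were THI2.2, AT2G47780 (-4.95 ± 0.20 in fh1-1 and -4.88 ± 0.20 with SMIFH2), AT1G70820 (5.06 ± 0.25 and 4.68 ± 0.25), AT5G33370 (5.17 ± 0.32 and 3.96 ± 0.32) and AOP3. AT2G23840 (4.13 ± 0.16 and 4.45 ± 0.16), AT1G06100 (4.59 ± 0.22 and 3.97 ± 0.22) and AT4G19530 (5.02 ± 0.20 and 3.39 ± 0.20) completed the 8. Across the 16554 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.74 (Spearman's rho 0.59), and 69% of genes had the same sign in both. The covariance was 0.246. In 20 simulations of unchanged groups it was 0.000, which follows from drawing the noise of each group separately. The simulations therefore do not test handling shared between groups. With single arrays in place of group means, the 4 pairings of an fh1-1 array with a SMIFH2 array gave r = 0.64 to 0.66.

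Of the 1288 genes higher with SMIFH2, 937 (72.7%) were also higher in fh1-1, against 140 for independent lists, and of the 1171 lower genes 782 (66.8%) were also lower, against 137. Fisher's exact test, one-sided, gave base-10 logarithms of p of -705 and -493, and 22 genes passed in opposite directions. The test counts genes as independent, which they are not, so these p values do not measure variation between pools. LHB1B2 had means of 10.84 in fh1-1 and 10.94 with SMIFH2, but of 6.01 and 9.40 in their controls. The size of an effect thus depends on its control too. Among the 1719 genes changed the same way in both, 1134 (66%) had the larger absolute log2 fold change in fh1-1. Fewer genes were shared in this way whichever single array was left out, and the fewest without array 1 or 2 of SMIFH2. Each omission leaves 1 array in its group.

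**Figure D3:**
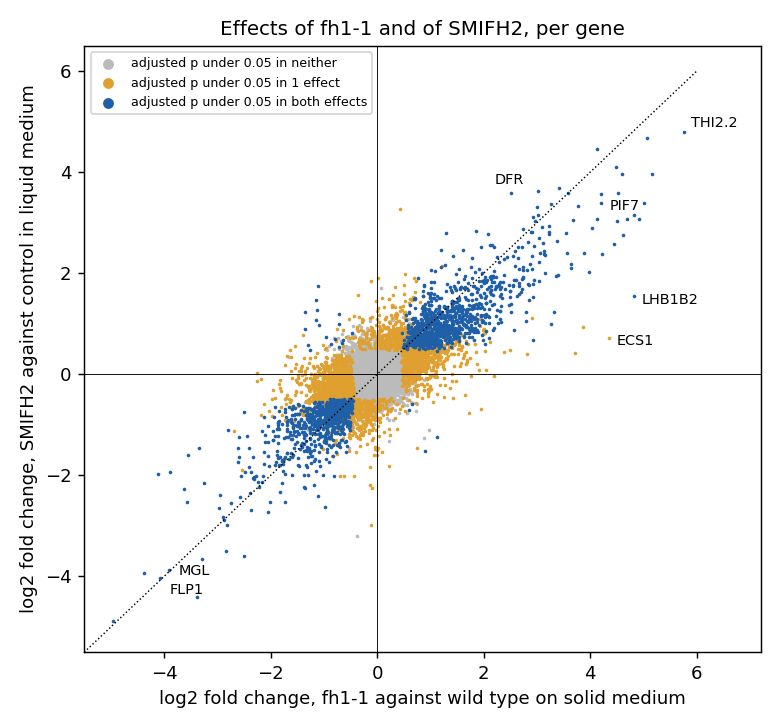
Log2 fold change of each of the 16554 genes in fh1-1 against wild type on solid medium (horizontal axis) and with SMIFH2 against control in liquid medium (vertical axis), coloured by whether the adjusted p was under 0.05 in neither, 1 or both effects, with a dotted line of equal change. The correlation across genes was 0.74, and LHB1B2 and ECS1 lay below the line of equal change.

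The third comparison set the 2 untreated wild-type groups against each other; they differed in medium, in the transfer itself and in light, which cannot be told apart. ECS1 rose by 5.01 ± 0.47 in liquid medium (log2, SE, n = 2 arrays per group), and LHB1B2 rose by 3.38 ± 0.18. The rise of ECS1 was 4.27 without array 1 of the liquid control and 5.76 without array 2. PDF1.4 (AT1G19610), a plant defensin, rose by 3.27 ± 0.22, BGLU25 (AT3G03640), a beta-glucosidase, by 2.55 ± 0.16, and CHX16 (AT1G64170), a cation exchanger, by 2.37 ± 0.20. Of 6 root markers 5 fell, with JAL22 at -1.65 ± 0.18 and JAL33 at -1.08 ± 0.16 (list adjusted p = 1.8e-07, and adjusted p = 0.12 with an estimated correlation). LBD29 (AT3G58190), a regulator of lateral roots, fell by 1.49 ± 0.15.

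The peroxidase PRXCA (AT3G49110) rose by 2.25 ± 0.30, from a mean of 1.68 under the 25th percentile of every array, the pectin methylesterase ATPMEPCRB (AT4G02330) by 1.89 ± 0.18 and BGLU45 (AT1G61810) by 1.88 ± 0.17. The sugar transporter SWEET3 (AT5G53190) fell by 1.44 ± 0.15 to a mean of 2.23, near that percentile, the pectin methylesterase ATPMEPCRD (AT2G43050) by 1.41 ± 0.19 and the carboxypeptidase-like scpl48 (AT3G45010) by 1.39 ± 0.20. These passed in limma at adjusted p values from 4.6e-05 to 0.0044. Other genes among the 8 largest falls passed less firmly: hemb2 (AT1G44318), -1.66 ± 0.30 at 0.014, RTFL7, -1.54 ± 0.35 at 0.034, and EXPA25 (AT5G39300), -1.41 ± 0.32 at 0.035. Without array 2 of wild type on solid medium their adjusted p values were 0.056, 0.16 and 0.2. hemb2 also missed the threshold without array 1 of the liquid control (0.064), and EXPA25 and RTFL7 without array 2 of that control (0.16 and 0.081) or array 1 of wild type on solid medium (0.068 and 0.1). The change of RTFL7 itself was -0.90 without array 2 of the liquid control and -2.19 without array 1. Leaving out either fh1-1 array ended the call of EXPA25 and RTFL7 (0.058 each), and leaving out either SMIFH2 array that of RTFL7 (0.051). Over every probe set all 3 missed the threshold (0.072, 0.12 and 0.12), as did RTFL7 in the fit of the 4 wild-type arrays (0.095). Over 16 alternatives the ranges were 0.0039 to 0.072 for hemb2, 0.0024 to 0.16 for RTFL7 and 0.014 to 0.2 for EXPA25.

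In total 779 genes passed, 368 higher and 411 lower in liquid medium, of which 172 and 179 were at least 2-fold changed. A fit of the 4 wild-type arrays alone, with fewer arrays behind the spread, gave 321 genes. Leaving out any single one of the 8 arrays, also of the 2 groups not compared, gave fewer genes. Each omission leaves 1 array in its group. The share of calls that were higher, 47.2%, was 53.8% with cyclic loess and 56.3% over every probe set.

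The root markers had 5 of 6 members lower in liquid medium, or 6 over the list alone, with a median of -0.91 and an adjusted p of 1.8e-07 (adjusted p = 0.12 with an estimated correlation). The photosynthesis list had 6 of 11 higher, or 7 over the list alone, among them PSBW (AT2G30570) at 1.13 ± 0.15, with a median of 0.65 and an adjusted p of 3.9e-08 (adjusted p = 0.076 with an estimated correlation). The shoot markers had 4 of 9 higher, or 6 over the list alone, with a median of 0.58 and an adjusted p of 1.2e-06 (adjusted p = 0.12 with an estimated correlation). The guard cell regulator FMA (AT3G24140) rose by 0.92 ± 0.18 and YAB2 (AT1G08465) by 0.88 ± 0.20. FMA missed the threshold without any single array of wild type on solid medium (0.059 and 0.11) or of the liquid control (0.058 and 0.074) or over every probe set (0.07), in a range from 0.0088 to 0.11. YAB2, at 0.038, missed it without any single array other than array 1 of the liquid control, at 0.054 without either fh1-1 array, 0.065 without either SMIFH2 array, 0.12 and 0.16 without array 1 or 2 of wild type on solid medium, and 0.15 without array 2 of the liquid control. It was 0.11 over every probe set and 0.1 in the fit of the 4 wild-type arrays, in a range from 0.013 to 0.16.

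The xyloglucan endotransglucosylases, enzymes that remodel cell walls, had 1 of 10 higher, or 3 over the list alone, with a median of 0.28 and an adjusted p of 0.018 (adjusted p = 0.18 with an estimated correlation). That gene was XTH16 (AT3G23730) at 1.19 ± 0.24, which missed the threshold without array 2 of wild type on solid medium (0.12) or array 2 of the liquid control (0.11), over every probe set (0.092) or in the fit of the 4 wild-type arrays (0.087), in a range from 0.0085 to 0.12. Of 22 expansins EXPA25 and EXPB3 (-1.26 ± 0.17) fell and EXPA16 (0.85 ± 0.16) rose, or 6 fell and 1 rose over the list alone, with a median of -0.20 and an adjusted p of 0.045 (adjusted p = 0.18 with an estimated correlation). EXPA16 missed the threshold without array 1 of wild type on solid medium (0.083) or array 2 of the liquid control (0.073), over every probe set (0.056) or in the fit of the 4 wild-type arrays (0.072), in a range from 0.011 to 0.083. The expansin call ended without array 1 (0.054) or 2 (0.1) of wild type on solid medium or array 2 of the liquid control (0.2), in a range from 0.017 to 0.2. When the third of probe sets with the lowest mean level was left out, the expansin and the xyloglucan list calls both ended (0.071 each); the latter ranged from 0.014 to 0.18. The list adjusted p was 0.14 for formins, of which 0 of 9 passed, or 2 higher over the list alone, and for senescence and autophagy, 0.21 for cell cycle and histone genes, 0.38 for abscisic acid, cold and drought, and 0.62 to 0.97 for the other 9 lists. Median, mean and test differed in sign for microtubule genes (0.11, -0.01, up), for pollen and flower markers (0.02, 0.01, down) and for abscisic acid, cold and drought (-0.00, 0.27, up).

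The medium effect shares control arrays with each of the other effects. It correlated with the fh1-1 effect at r = 0.48 across genes, where simulated unchanged groups gave 0.50, but the covariance was 0.118 against a simulated 0.019. Of the genes higher in liquid medium 222 were also higher in fh1-1 (40 for independent lists), 275 were lower in both (48), and 34 passed in opposite directions. With the SMIFH2 effect the correlation was -0.08, against a simulated -0.50, and the covariance -0.017 against -0.019. There 116 genes were higher in both (28.6 for independent lists), 48 lower in both (29.1) and 169 opposite. The controls are too few to be split with 2 arrays in each part. For fh1-1, part of the excess of genes changed the same way may come from the shared arrays. In the SMIFH2 and medium effects the shared arrays enter with opposite signs. Their chance values may thus add to the 169 opposite genes, but not to those higher or lower in both.

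A last comparison tested whether the SMIFH2 effect and the fh1-1 effect differed from each other. LHB1B2 differed by -3.29 ± 0.26, with a mean of 9.40 in the liquid control, and ECS1 differed by -3.63 ± 0.67 (SE, n = 2 arrays per group). BGLU45 differed by -2.42 ± 0.24, BGLU33 (AT2G32860) by -1.95 ± 0.26, CHX16 by -1.95 ± 0.29 and KIN2 (AT5G15970) by -1.84 ± 0.28. In the other direction, BGLU28 (AT2G44460) differed by 1.89 ± 0.24, SWEET3 by 1.65 ± 0.21, with means of 1.83 in fh1-1 and 2.04 with SMIFH2 that were not shown to be above background, CTF2A (AT2G35660) by 1.48 ± 0.26, UGT71C1 (AT2G29750), a UDP-glycosyltransferase, by 1.28 ± 0.21 and JAL33 by 1.24 ± 0.22. ATPMEPCRB differed by -1.48 ± 0.25 and EXPA16 by -1.30 ± 0.22. Adjusted p values ran from 0.0016 for LHB1B2 to 0.046 for ECS1. Tested over every probe set, none of these 13 genes passed, at adjusted p values from 0.06 for LHB1B2 to 0.22 for ECS1. The difference of ECS1 was -2.89 without array 1 of the liquid control and -4.38 without array 2. ECS1 also missed the threshold with cyclic loess (0.051), and BGLU45 without array 2 of fh1-1 (0.051). The other 11 genes apart from LHB1B2 missed it without either fh1-1 array and without either SMIFH2 array (0.052 to 0.2), and 10 of them, all but BGLU28, without array 2 of wild type on solid medium (0.06 to 0.13). Without array 1 of that group 3 missed it (0.076 to 0.098), and without array 1 or 2 of the liquid control 4 (0.056 to 0.076) or 5 (0.051 to 0.091).

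In total 123 genes differed at an adjusted p under 0.05 in limma, 59 with a higher and 64 with a lower effect of SMIFH2, all by at least 2-fold. Of these, 114 also passed in the medium comparison, and 6 passed directly between SMIFH2 in liquid and fh1-1 on solid medium. In the medium comparison 122 had the opposite sign, and the wild-type arrays enter both contrasts, with opposite signs. The count fell whichever single array was left out, which leaves 1 array in its group. No named difference changed sign. Without array 1 or 2 of fh1-1, BGLU28 differed by 2.03 or 1.74 and ECS1 by -3.34 or -3.92. How far the count fell depended on which array was left out, although each omission left the same number of arrays. The reason was not tested. Tested over every probe set, 3 probe sets passed.

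The root markers differed with a median of 1.11 and an adjusted p of 2.7e-07 (adjusted p = 0.17 with an estimated correlation), with 1 of 6 genes past the threshold or 5 over the list alone. The photosynthesis list differed with a median of -0.56 and an adjusted p of 8.3e-08 (adjusted p = 0.082 with an estimated correlation), with LHB1B2 alone of 11 past the threshold or 6 over the list alone. The shoot markers differed with a median of -0.56 and an adjusted p of 3.3e-05 (adjusted p = 0.18 with an estimated correlation), with 0 of 9 genes past the threshold or 2 over the list alone. The other 15 lists did not pass, at list adjusted p values from 0.073 to 0.99; formins gave a median of -0.21 at 0.23. For the unfolded protein response (0.03, -0.04, down) and for pollen and flower markers (-0.00, 0.01, up), median, mean and test differed in sign.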

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

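The held-out test in this part was chosen only after the result was seen. The test of the difference between the SMIFH2 and fh1-1 effects was planned, and 123 genes passed it in limma. Those named by rule with a higher effect of SMIFH2 were BGLU28 (1.89), SWEET3 (1.65), CTF2A (1.48), UGT71C1 (1.28) and JAL33 (1.24). Those with a lower effect were ECS1 (-3.63), LHB1B2 (-3.29), BGLU45 (-2.42), BGLU33 (-1.95), CHX16 (-1.95), KIN2 (-1.84), ATPMEPCRB (-1.48) and EXPA16 (-1.30). The lists that differed had medians of -0.56 for photosynthesis, 1.11 for root markers and -0.56 for shoot markers. In camera with an estimated correlation they missed the threshold (adjusted p = 0.082, 0.17 and 0.18).

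Of the 123 genes, 122 had the opposite sign in the medium comparison, which uses the same wild-type arrays with the opposite sign, so chance values of those arrays may produce this pattern. To see whether medium effects recur, the 779 genes with the largest medium difference were picked on 1 pair of wild-type arrays and measured on the other pair. Their median medium effect there was 0.64 or 0.67, by which pair was picked, against 0.08 or 0.11 between fh1-1 on solid and SMIFH2 in liquid medium. The medium effect of these 779 genes was thus seen again in arrays not used to pick them. The 123 genes were not picked or measured in this way, so chance values stay open for them. Of the 123 genes, 114 passed in the medium comparison, but 6 passed between fh1-1 on solid and SMIFH2 in liquid medium. The difference of effects equals that direct change minus the medium effect. Medium, transfer or light may have altered these genes in wild type and done so less in impaired seedlings. This would give the same pattern, and as a cause it stays open and untested. The count of 123 genes itself fell whichever single array was left out, which leaves 1 array in its group. How far it fell depended on which array was left out, although each omission left the same number of arrays. The reason was not tested.

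Signal also appeared in the 21662 probe sets that no comparison of named genes uses. Tested apart in limma, 2838 of these passed in fh1-1, 1405 with SMIFH2 and 82 in liquid against solid medium.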

How the results depend on the processing

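No gene named by the rule and no list fixed beforehand that passed changed direction under any alternative, but the balance of higher and lower calls did. Genes of the direct comparison and the lists chosen later were not followed in this way. The share of calls that were higher was 48.2% in fh1-1 (46.5% to 55.4% over the alternatives without a fold threshold), 52.4% with SMIFH2 (49.8% to 58.6%) and 47.2% for the medium (44.3% to 56.3%). For the difference it was 48% (25% without array 2 of SMIFH2, 33.3% over every probe set, 37.5% without array 2 of wild type on solid medium, and 55.6% without array 1 of SMIFH2). The correlation of the fh1-1 and SMIFH2 effects was 0.63 over every probe set, 0.78 without the third of probe sets with the lowest mean level, and 0.70 to 0.74 when single arrays were left out. Over every probe set 6205 passed in fh1-1 and 3 in the difference of effects. With a 2-fold change and an unadjusted p under 0.05 the counts were 1428 in fh1-1, 935 with SMIFH2, 403 for the medium, 478 for the difference and 622 for genes shared by both effects; with a 2-fold change and an adjusted p they were 1417, 916, 351, 123 and 616, the last an alternative chosen after seeing the data, as were the other alternatives for shared genes except the first threshold. These 2 thresholds ask for larger changes by construction. The fit of 4 arrays, with fewer arrays by construction, gave 321 genes for the medium, and the trended robust prior 296 for the difference, for which the cause was not tested. Leaving out single arrays gave 2056 (array 1 of fh1-1) to 3952 genes in fh1-1, 1250 (array 1 of SMIFH2) to 2396 with SMIFH2, 284 (array 2 of wild type on solid medium) to 599 for the medium, 2 (array 2 of fh1-1) to 117 for the difference and 996 (array 1 of SMIFH2) to 1553 shared genes. With an estimated correlation 1 list passed in fh1-1, and 0 with SMIFH2, 0 for the medium and 0 for the difference; fry, which tests another hypothesis, gave 8, 10, 6 and 4. Without the third of probe sets with the lowest mean level 3 lists passed in fh1-1 and 3 for the medium. In that setting the abscisic acid, cold and drought list had under 5 members left and was not tested in fh1-1. Leaving out single arrays gave 3 to 5 lists in fh1-1, 5 with SMIFH2, 4 to 6 for the medium and 3 to 4 for the difference. For named genes, 745 of 779 values under other settings and 678 of 792 with an array left out stayed on their side of the threshold, and the others missed it; for lists these were 156 of 176 and 136 of 144. No scaling shifted the median of all genes by more than 0.046.

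With the repeat number as a replicate block, 3543 genes passed in fh1-1, 2248 with SMIFH2, 645 for the medium and 77 for the difference, with 1592 shared genes and a correlation of 0.74. Of the genes named by rule, ECS1 (0.075), JAL33 (0.062), EXPA16 (0.051), CTF2A (0.05) and UGT71C1 (0.05) then missed the threshold in the difference, and YAB2 (0.058) and EXPA25 (0.051) in the medium comparison. Of the other members named, COR47 missed it in fh1-1 (0.057), and JAL33 (0.061) and AKINBETA1 (0.051) with SMIFH2. Arrays of the same number deviated from their group means with correlations from -0.028 to 0.051 over 6 pairs of groups, and they share only a number.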

Other observations

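The 4 lists described first, the direct comparison and the tests of explanations were chosen only after the results were seen, whereas the clock, root marker, shoot marker and photosynthesis lists were fixed before. The lists of amino acid breakdown, the NDH complex and tetrapyrrole synthesis were drawn up after some of their members had been seen to change, so their members are described here without a list test. Of 9 genes of amino acid breakdown, 6 were lower in fh1-1 (7 over the list alone) and 7 with SMIFH2 (also 7), with medians of -0.56 and -1.06. Besides MGL, AT1G21400, a subunit of the branched-chain keto acid dehydrogenase, changed by -2.82 ± 0.18 and -2.98 ± 0.18 (SE, n = 2 arrays per group). AT4G33150, which encodes an enzyme of lysine breakdown, changed by -2.90 ± 0.17 and -2.83 ± 0.17.

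Of 8 nuclear genes of the chloroplast NDH complex and its assembly, 8 were higher in fh1-1 and 7 with SMIFH2 (8 over the list alone), with medians of 1.31 and 1.13. NdhL changed by 2.62 ± 0.16 and 1.56 ± 0.16, and NdhN by 1.68 ± 0.16 and 1.21 ± 0.16. Of 8 genes of tetrapyrrole synthesis, 4 were higher and 1 lower in fh1-1, and 2 higher with SMIFH2. The 63 plastid-encoded genes had a median of 0.08 in fh1-1, with 8 up and 1 down, and the list passed upward in limma's camera (adjusted p = 0.0073, and adjusted p = 0.48 with an estimated correlation). With SMIFH2 their median was -0.10, with 1 up and 2 down (adjusted p = 0.11, and adjusted p = 0.67 with an estimated correlation). For the medium 60 of the 63 lay above 0 (adjusted p = 3.8e-05, and adjusted p = 0.28 with an estimated correlation), and for the difference of effects 57 lay below 0 (adjusted p = 2.8e-06, and adjusted p = 0.23 with an estimated correlation). Their median level was 11.9, on arrays whose highest values were 13.33 to 13.46, and how far such probes can still rise was not tested.

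Set directly against each other, the arrays of SMIFH2 in liquid and fh1-1 on solid medium differed in 24 genes, 19 higher and 5 lower with SMIFH2, and 1201 genes had an unadjusted p under 0.05, where 828 are expected by chance. Of the 21662 other probe sets 0 passed in this comparison. The 24 genes included the defensin gene PDF1.4 (2.01 ± 0.22), BGLU25 (1.98 ± 0.16) and AT5G10695 (-1.63 ± 0.16). This comparison differs in genotype, drug, medium and light at once.

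The effects of fh1-1 and SMIFH2 were alike across genes, and a trend with signal level left by the authors' normalization may produce that; within 10 groups of genes of like mean level the median correlation was 0.70, from 0.11 in the dimmest to 0.85, which argues against it. Whether both labels held one kind of material stays open, because FH1 had no probe set and the 24 genes above could differ by medium alone. The real split of these 4 arrays gave 15 genes and the highest other split 0; 1 of 3 splits was as large, and 3 are too few for a share under 0.05. A different time of harvest stays open too. Of the clock list only 1 gene was measured, GI, at 0.27 ± 0.26 in fh1-1 and -0.16 ± 0.26 with SMIFH2. COR27, outside that list but tied to the clock and to cold, changed by -2.04 ± 0.17 and -2.72 ± 0.17. No label gives a batch, and a shared handling batch or a difference in genetic background between seed lots was not tested. A shared response to impaired formins stays an open, untested hypothesis.

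The rise of photosynthesis genes may come from a larger share of shoot tissue in the pools. With SMIFH2 the root markers had a median of 0.45 (SE of the mean across the 6 genes 0.11), and 6 of 6 lay above 0. The same genes had a median of -0.91 in liquid against solid medium in wild type. Their rise goes against a larger shoot share only if these genes follow the amount of root tissue, which was not tested. In fh1-1 the leaf development markers YAB2, MUTE, FMA, YAB3 and SPCH had a median of 0.57 (SD 0.48) against 1.75 for photosynthesis. FMA had means of 4.37 in wild type and 5.48 in fh1-1, against a median level of 9.03 for the photosynthesis genes. How level affects the size of a change was not tested, so the lower median does not decide whether tissue share was the whole cause. Tissue share, as a part or the whole, stays open in fh1-1, where the root markers had a median of -0.48. The root markers are 6 genes of related function, and a change in those genes alone would look the same.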
